A study of Pimephales promelas with 24 samples.

How the data were processed

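Liver RNA of 24 fathead minnows was measured on 2-colour Agilent oligonucleotide arrays. Per the labels, RNA was isolated with TRIzol, labelled with Agilent's Quick Amp kit, and 825 ng of each Cy5-labelled sample was combined with 825 ng of a Cy3-labelled reference pooled from the 6 control fish (3 females, 3 males). Cy5 was always the fish and no array had the dyes exchanged, so a dye effect on a probe is the same on every array and falls out of each difference between groups. The fish came from breeding pairs in chambers of 5.3 L within a column of 42.1 L. The labels call the 3 fish of each group biological replicates.

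Per the file headers, the authors quantified each scan with Agilent Feature Extraction 9.5.1.1, which gave for every spot a mean signal intensity and a local background intensity in each channel, with no normalization, and processed intensities that were background-subtracted and dye-normalized within the array. The deposited scanner files also hold the log10 ratio of the processed intensities of Cy5 over Cy3. The deposited value table holds log2 ratios of Cy5 over Cy3 per spot; the authors name limma without a version for this step, and any scaling between arrays is not stated. Its 24 columns had medians of -0.00128 to 0.00914 and correlated across spots with the log2 ratio of the scanner signals of the same array at 0.952 to 0.968. Files of male control replicates 1 and 3 held rounded values, with the same columns.

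Each array had 44407 spots, of which 1417 were controls and 42990 were those of 21495 probes with 2 spots each. Signal intensities were corrected by normexp on the background median (offset 50) and normalized by loess within each array in limma 3.58.1 (under R 4.3.3), with control spots and outlier spots (0 to 119 per array) left out of the curve and outlier spots left out of the means. Nothing was scaled between arrays. The spots of a probe were averaged, and 11755 probes were kept that were well above background in Cy5 on both spots and on all arrays of at least 1 group. Median net signals ranged from 54.0 to 145 in Cy5 and from 119 to 182 in Cy3, with at most 14 saturated spots per array. Arrays give no counts, so their number limits the precision.

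Group means of the 8 groups of sex and water were fitted to all 24 arrays in limma, with moderated tests and Benjamini-Hochberg adjusted p under 0.05 within each comparison. Comparisons were each effluent against the control within a sex, male against female controls, the male minus the female response to each effluent, and a moderated F-test over the 3 effluents within a sex. Choices of comparisons, tests, settings, gene lists and named genes were made before the data were examined. Per comparison, the rule named up to 8 genes in each direction that carried a readable name, passed and had no overlap between the fish of both groups; where fewer than 5 passed, it named the 5 with the smallest p, and zona pellucida glycoprotein 3 in any case as a member of the egg yolk and envelope list. For the F-tests and the male minus female responses it named the 5 with the smallest p. Unnamed probes were given by ID if they passed and, where 2 groups were compared, had no overlap between the fish. Of these, at most 2 in each direction were given, by the largest change. Similarity of responses was measured across probes by Pearson's r, Spearman's rho and the covariance, beside 100 simulations of unchanged groups that shared the control fish. For slide 4, 100 further simulations drew 6 of the 12 males' deviations from their group means with random signs.

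Names on the array were mostly those of assembled contigs: 6095 accessions in them were looked up in a reference table of 64593 genes of the species and 0 matched, so no gene could be assigned from it. Of 39 gene lists fixed beforehand, 7 had a gene with a readable name on the array and 6 had 1 that was kept: egg yolk and envelope (zona pellucida glycoprotein 3), estrogen response (estrogen receptor alpha), complement (complement C3S), acute phase (pentraxin), cell cycle (cyclin B1) and exocrine pancreas (alpha amylase). A list needed 3 genes, so none was tested; the list of targets of the aryl hydrocarbon receptor and the list of ovary markers had no readable member.

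The 24 arrays were on 7 slides and in 3 scans. All 3 UTK males were on slide 4 with male control replicate 3. Each result was fitted again with slide and with scan as a block, and within each slide or scan that held all groups compared, with the spread pooled over all cells of group and batch, so that a lone array was taken to vary like the others. Same-numbered fish were taken as paired only where the correlation of their deviations from the group means exceeded 0.1 in all 3 pairs, which held for male and female controls (0.132 to 0.203) and for no comparison of an effluent with its control. No fit paired these controls by themselves: between the sexes, replicate number was a block shared by all 24 arrays. Alternatives were the scanner's processed signals, normexp with offset 0, median centring in place of loess, quantile scaling of average intensities after loess, Cy5 alone with quantile scaling, no filter, a filter on all arrays, replicate number as a block, the compared groups alone, array weights, the deposited log2 ratios, and leaving out each fish in turn. Added after seeing the data were a comparison of males with females among exposed fish, with its alternatives, and fits without female control replicate 3 (with and without scan as a block) for results that leaving out single fish did not cover.

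The steps were tested on simulated data in which, among 11755 probes, 100 changed by 1 log2 unit and 100 others by 2 in the same data. A log2 change of 1 was recovered for 33% to 42% of the probes in comparisons of 3 fish with 3, and a change of 2 for 76% to 87%. For the male minus female responses these shares were 6% to 13% and 51% to 55%. The simulated noise was normal, independent between probes and alike for all fish, with no slide or scan effect and no array standing apart. On the real arrays the shares may therefore differ.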

Results

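Gene expression was measured in the livers of sexually mature fathead minnows (Pimephales promelas), a small fish used in water quality tests. Breeding pairs were held for 6 days in river water (the control), in untreated kraft effluent diluted to 10% (UTK), in treated kraft effluent diluted to 25% (TK) or in undiluted (100%) final effluent of a mill that runs several pulping processes (CMO). Kraft pulping is a chemical way of freeing wood fibres. Livers of 3 females and 3 males from each water gave 24 arrays in 8 groups of 3 fish. On every array the Cy5-labelled RNA of a single fish met the Cy3-labelled RNA of a pool of all 6 control fish, so each value is a log2 ratio of a fish to that pool. Of 21495 probes on the array, 11755 were kept. The share of probe spots well above background ranged from 45.6% to 65.0% in Cy5 (median 54.9%) and from 51.7% to 63.8% in Cy3 (median 56.7%). Only 35 probes carried a readable gene name, and 11 of these were kept: alpha amylase, CD18 type 2, complement C3S, cyclin B1, cytochrome b, estrogen receptor alpha, myocyte enhancer factor 2a, pentraxin, taurine transporter, zona pellucida glycoprotein 3 and a clone named 149D2R. The files do not pair the other probes with genes, so those are given by probe ID alone. The number of fish limits the precision of every value.

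Females and males parted on the second principal component (13.8% of the variance), apart from a single fish. All 12 male arrays and female control replicate 3 lay below 0 on it, and the other 11 female arrays above. The first component (28.3%) placed female control replicate 3 at a score of -139.9, against -41.7 to 42.1 for the other 23 arrays. In that fish zona pellucida glycoprotein 3, an egg envelope protein, stood at a log2 ratio of 2.84 and cyclin B1, a cyclin of cell division, at 1.30. The other 23 arrays lay between -6.36 and -4.11 for the former and between -4.40 and -1.74 for the latter. Across probes, its log2 ratios correlated with those of the other arrays at r from -0.56 to -0.13, while the other 23 arrays correlated with each other at 0.34 to 0.82. This fish is 1 of 3 in the control group of every female comparison and 1 of 6 in the pool.

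**Figure D1:**
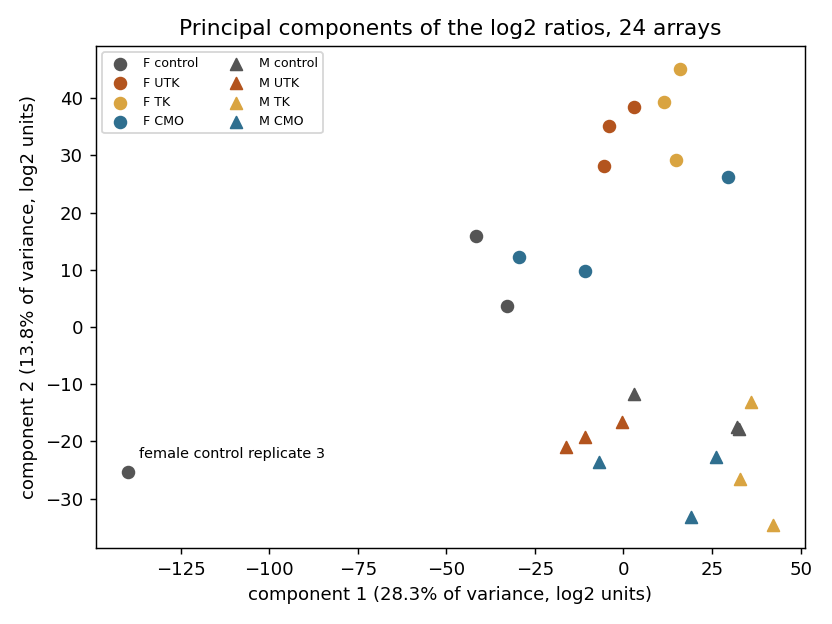
Scores of the 24 arrays on the first and second principal components of the log2 ratios (both axes in log2 units); each point is a fish, circles are females, triangles are males and colours are the waters. Female control replicate 3 lies at -139.9 on the first component, and the other 23 fish lie between -41.7 and 42.1.

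The question put to UTK females against control females was how female liver responded to untreated kraft effluent. Cyclin B1 (probe EA_Pp_51259), which drives entry into mitosis, fell 6.30-fold, from a log2 ratio of -0.77 ± 1.80 (SD, n = 3) in controls to -3.43 ± 0.06 (n = 3), a log2 change of -2.66 ± 0.67 (SE). CD18 type 2 (EA_Pp_68251), a form of the beta subunit of leukocyte integrins, rose 1.76-fold, by 0.82 ± 0.25 on the log2 scale. Zona pellucida glycoprotein 3 (EA_Pp_69893) differed by -3.47 ± 1.22, complement C3S (EA_Pp_69074), a form of the central complement protein, by 1.33 ± 0.67 and cytochrome b (EA_Pp_65893), a subunit of mitochondrial complex III, by 0.53 ± 0.34, and these did not pass. Among unnamed probes that passed without overlap of the fish, the steepest rise was that of EA_Pp_58857 (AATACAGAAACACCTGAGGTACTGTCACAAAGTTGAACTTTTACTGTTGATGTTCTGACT) and EA_Pp_54473 (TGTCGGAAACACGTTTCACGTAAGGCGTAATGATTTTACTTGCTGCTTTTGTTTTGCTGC), by 5.15 ± 0.57 and 4.51 ± 0.47, sizes that are inexact because each was well above background in only 1 of 3 control females. EA_Pp_58857 averaged 5.40 ± 0.62 (SD, n = 3) in UTK females and 0.25 ± 0.47 in control females. Names of EA_Pp_58857 and EA_Pp_54473 on the array share a contig number, so the 2 may not be separate transcripts. EA_Pp_57767 fell by 4.66 ± 1.23 (SE). In limma, 965 of 11755 probes passed (318 up, 647 down), with adjusted p = 0.0300 for cyclin B1, 0.0499 for CD18 type 2, 0.0758 for zona pellucida glycoprotein 3, 0.207 for complement C3S, 0.329 for cytochrome b, 2.41e-04 for EA_Pp_58857, 1.84e-04 for EA_Pp_54473 and 0.0328 for EA_Pp_57767.

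The count for UTK females rested on single fish and fell with slide or scan as a block. It was 8 (7 up, 1 down) without female control replicate 3, 23 and 33 without UTK replicates 1 and 2, 481 without UTK replicate 3, and 1580 and 1870 without control replicates 1 and 2. Without female control replicate 3, cyclin B1 stood at -1.62 (limma adjusted p = 0.227; 0.0144 to 0.411 over its 20 alternatives), CD18 type 2 at 0.67 (adjusted p = 0.307; 0.0345 to 0.695) and EA_Pp_57767 at -2.23 (adjusted p = 0.150; 0.00754 to 0.338). Calls of cyclin B1, CD18 type 2 and EA_Pp_57767 were also lost without any 1 of the 3 UTK females, whereas zona pellucida glycoprotein 3 passed without control replicate 1 (-5.03, limma adjusted p = 0.0137) or 2 (-4.42, adjusted p = 0.0314; 0.0137 to 0.435 over its alternatives). Most of its difference came from female control replicate 3, without which it was -0.95 (limma adjusted p = 0.241), and cytochrome b then differed by 0.15. EA_Pp_58857 and EA_Pp_54473 passed in limma under 17 of their 19 alternatives, missing at adjusted p = 0.0549 with slide as a block and 0.0996 with the compared groups fitted alone. With scan as a block limma called 7 probes (7 up), with cyclin B1 at -2.53 (adjusted p = 0.0765) and CD18 type 2 at 0.72 (adjusted p = 0.106). Slide as a block left 1 probe (1 up) in limma, cyclin B1 stood at -2.34 (adjusted p = 0.165) and CD18 type 2 at 0.70 (adjusted p = 0.191). Across probes the blocked log2 changes still correlated with the unblocked ones, at r = 0.979 for scan and 0.969 for slide. An unadjusted p under 0.05 was reached in limma by 2916 and 2322 probes, against 3223 unblocked. Within slide 2 (1 UTK fish and 2 controls) limma called 0 probes (2094 at an unadjusted p under 0.05), within slide 6 (1 and 1) 0 (367), within scan 1 (1 and 2) 0 (2227) and within scan 2 (1 and 1) 2. Scaling by the array median in place of loess moved the median of all probes in this comparison from 0.08 to -0.17 log2 units and left 4 probes (4 up, 0 down), against 6 (4 up, 2 down) with the scanner's processed signals, 4 (4 up, 0 down) with Cy5 alone and 6 (5 up, 1 down) with the deposited log2 ratios. Fitting the compared groups alone left 0 in limma (1817 unadjusted).

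**Figure D2:**
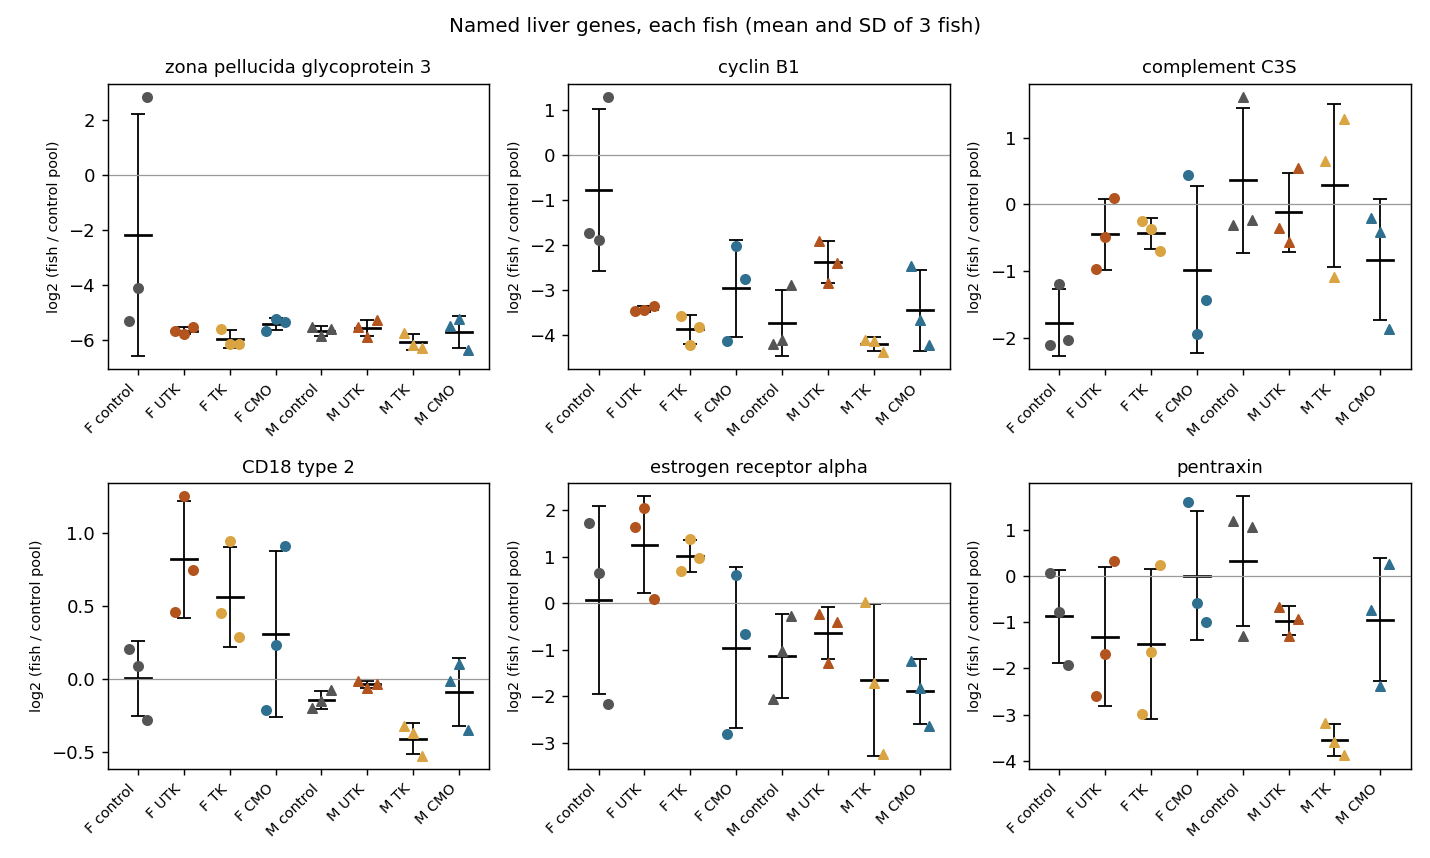
Log2 ratio of each fish to the control pool (vertical axes, log2 units) for 6 genes with readable names, with each point a fish and each bar the mean and SD of 3 fish, by sex and water. Zona pellucida glycoprotein 3 stands at 2.84 in female control replicate 3 and between -6.36 and -4.11 in the other 23 fish.

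TK females against control females put the same question for treated kraft effluent. Cyclin B1 fell 8.63-fold, to a log2 ratio of -3.88 ± 0.33 (SD, n = 3), a change of -3.11 ± 0.67 (SE). Zona pellucida glycoprotein 3, which fish make in liver or ovary for the egg envelope, fell 13.6-fold, from -2.20 ± 4.40 (SD, n = 3) in controls to -5.97 ± 0.32 (n = 3), a change of -3.77 ± 1.22 (SE). CD18 type 2 differed by 0.56 ± 0.25, complement C3S by 1.34 ± 0.67 and clone 149D2R (EA_Pp_71488) by 0.27 ± 0.14, and these did not pass. Among unnamed probes EA_Pp_67150 rose by 3.24 ± 0.81 and EA_Pp_53813 fell by 5.67 ± 1.02. EA_Pp_68204 changed by 4.68 ± 1.20 (limma adjusted p = 0.0164), inexact because only 1 of 3 control females was well above background. Without female control replicate 3 it stood at 4.43 (limma adjusted p = 0.0941). EA_Pp_57767 changed by -5.67 ± 1.23 (limma adjusted p = 0.00749), and by -3.24 without that fish (limma adjusted p = 0.0157). In limma, 1686 of 11755 probes passed (460 up, 1226 down), with adjusted p = 0.00745 for cyclin B1, 0.0458 for zona pellucida glycoprotein 3, 0.135 for CD18 type 2, 0.180 for complement C3S, 0.189 for 149D2R, 0.0148 for EA_Pp_67150 and 0.00647 for EA_Pp_53813.

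Without female control replicate 3 the TK count was 297 (28 up, 269 down), and it was 982 and 1023 without TK replicates 1 and 3. The egg envelope gene then stood at -1.25 (limma adjusted p = 0.0555; 0.00603 to 0.759 over its 20 alternatives) and EA_Pp_67150 at 2.18 (adjusted p = 0.122; 0.00425 to 0.694), and the call of the former was also lost without TK replicate 1, 2 or 3 (adjusted p = 0.0831, 0.0954 and 0.102). Cyclin B1 and EA_Pp_53813 passed without each single fish, but without female control replicate 3 their changes were smaller, at -2.07 (limma adjusted p = 0.0496) and -3.92 (adjusted p = 0.0181; 0.00303 to 0.694 over the alternatives of the latter). No slide held fish of both groups together. Blocking on slide, limma called 0 probes (819 at an unadjusted p under 0.05), with cyclin B1 at -2.09 (adjusted p = 0.698; 0.00425 to 0.698) and zona pellucida glycoprotein 3 at -2.81 (adjusted p = 0.759). With scan as a block 715 passed in limma (131 up, 584 down) and zona pellucida glycoprotein 3 stood at -3.20 (adjusted p = 0.169). With scan as a block and without female control replicate 3, 0 probes passed in limma (2032 unadjusted). Within scan 2 (2 TK fish, 1 control) 3 probes passed. Array-median scaling left 3 probes (3 up, 0 down), the scanner's processed signals 1 (0 up, 1 down), Cy5 alone 0 (1766 at an unadjusted p under 0.05 in limma) and the deposited log2 ratios 14 (5 up, 9 down). The compared groups fitted alone gave 0 in limma (2031 unadjusted), and array weights 996.

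CMO females against control females showed the same signs for cyclin B1 and zona pellucida glycoprotein 3, but nothing passed. Cyclin B1 differed by -2.20 ± 0.67 (SE; -2.97 ± 1.08, SD, n = 3, in CMO females) and zona pellucida glycoprotein 3 by -3.23 ± 1.22. Cytochrome b differed by 0.88 ± 0.34, alpha amylase (EA_Pp_50332), a digestive enzyme of the exocrine pancreas, by 1.60 ± 0.89 and 149D2R by 0.19 ± 0.14. In limma, 0 of 11755 probes passed at an adjusted p under 0.05 (2398 at an unadjusted p under 0.05), with adjusted p = 0.149 for cyclin B1, 0.174 for zona pellucida glycoprotein 3, 0.176 for cytochrome b, 0.312 for alpha amylase and 0.415 for 149D2R. When female control replicate 3 was left out, the differences were -1.16 for cyclin B1, -0.71 for zona pellucida glycoprotein 3, 0.50 for cytochrome b, 1.93 for alpha amylase and 0.13 for 149D2R. The count was 112 without control replicate 1, 467 without control replicate 2 and 11 with array weights. With slide as a block it was 0 in limma (146 unadjusted), with scan as a block 0 (2411), within slide 6 (1 and 1) 0 (212), within scan 1 (2 and 2) 70 (26 up, 44 down) and within scan 2 (1 and 1) 1.

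Changes in the 3 female comparisons, which share their 3 control fish, ran in parallel across probes. Cyclin B1 and zona pellucida glycoprotein 3 had lower means than in controls under all 3 effluents, though cyclin B1 did not pass under CMO and zona pellucida glycoprotein 3 passed under TK alone, and the differences of the latter were far smaller without female control replicate 3 (-0.95, -1.25 and -0.71 for UTK, TK and CMO). UTK and TK shared 117 probes that rose and 594 that fell, and 5 and 1 without female control replicate 3. Independent lists would share 12.4 and 67.5, but lists with the same controls are not independent, and the overlap of unchanged groups was not simulated. Across 11755 probes, which are not independent replicates, the log2 changes correlated at r = 0.870 (rho = 0.817) for UTK and TK, 0.825 (rho = 0.765) for UTK and CMO and 0.869 (rho = 0.810) for TK and CMO. In 100 simulations of unchanged groups against the same controls, r had a median of 0.542 and ranged from -0.465 to 0.965. Covariances were 0.627, 0.465 and 0.564 in the same order, against a simulated median of 0.0869. Without female control replicate 3 they were 0.286, 0.178 and 0.251 against 0.152, and r was 0.754, 0.641 and 0.740. The value of 0.152 is an uncertain yardstick, since its simulated deviations were still taken from group means that included that fish. Part of the resemblance may come from the shared controls, which are too few to divide.

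Exposed males were compared with control males, and few probes passed. TK males had pentraxin (EA_Pp_64247), of a family of acute-phase proteins, at -3.55 ± 0.35 (SD, n = 3; well above background in 2 of 3) against 0.32 ± 1.40 (n = 3), a difference of -3.86 ± 0.93 (SE) with no overlap of the fish that did not pass. Taurine transporter (EA_Pp_56251) differed by 1.07 ± 0.47 in TK males, alpha amylase by -1.88 ± 0.89, CD18 type 2 by -0.27 ± 0.25, cyclin B1 by -0.47 ± 0.67 and zona pellucida glycoprotein 3 by -0.41 ± 1.22. The unnamed probe EA_Pp_64895 rose 2.21-fold in TK males, from 0.12 ± 0.15 (SD, n = 3) to 1.26 ± 0.04 (n = 3). In UTK males cyclin B1 differed by 1.36 ± 0.67, pentraxin by -1.28 ± 0.93, alpha amylase by 0.69 ± 0.89, complement C3S by -0.48 ± 0.67, 149D2R by -0.14 ± 0.14 and zona pellucida glycoprotein 3 by 0.10 ± 1.22. In CMO males complement C3S differed by -1.19 ± 0.67, pentraxin by -1.27 ± 0.93, estrogen receptor alpha (EA_Pp_62566), a nuclear receptor for estrogens, by -0.77 ± 0.96, cytochrome b by 0.19 ± 0.34, 149D2R by -0.10 ± 0.14 and zona pellucida glycoprotein 3 by -0.03 ± 1.22. Each SE rests on a spread shared by all 8 groups. For zona pellucida glycoprotein 3 the control females widen it (SD 4.40). Its SD in males was 0.18 (control), 0.30 (UTK), 0.29 (TK) and 0.58 (CMO), so 1.22 overstates the error among males.

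In limma, 1 probe passed for TK males (EA_Pp_64895, adjusted p = 0.00613; 973 at an unadjusted p under 0.05), 0 for UTK males (760 unadjusted) and 0 for CMO males (450 unadjusted). Adjusted p was 0.313 for pentraxin in TK males, 0.553 to 0.959 for the other genes named there, 0.787 to 0.996 for those in UTK males and 1.00 for those in CMO males. The TK count was 44 without TK replicate 1, 6 without control replicate 3, 3 without control replicate 2 and 2 without control replicate 1 or TK replicate 2. The UTK count was 2 without control replicate 3, and the CMO count 1 without control replicate 3, CMO replicate 1 or CMO replicate 3. With slide as a block limma called 0 probes for UTK (117 unadjusted), 2 for TK and 0 for CMO (835 unadjusted); with scan as a block it called 0 (623), 0 (685) and 0 (522), and EA_Pp_64895 had an adjusted p of 0.0542 with scan and 0.512 with slide as a block (0.00190 to 1.00 over its 21 alternatives). All 3 UTK males were on slide 4, where limma called 0 probes against its 1 control male (125 unadjusted), and within scan 2 (3 and 2) it called 0 (233). For TK males 1 probe passed within slide 3 (2 and 1) and 0 within scan 2 (2 and 2; 486 unadjusted in limma). For CMO males 0 passed in limma within scan 1 (2 and 1; 542 unadjusted) and 1 within scan 2 (1 and 2), and no slide held both groups. Correlations of the log2 changes across probes were 0.220 for UTK and TK males, 0.575 for UTK and CMO and 0.534 for TK and CMO, against a simulated median of 0.541 (-0.147 to 0.907), and that for UTK and TK was 0.581 with the scanner's processed signals.

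Male and female controls differed in cyclin B1 and complement C3S, with the egg envelope gene falling short of the threshold. Cyclin B1 was 7.82-fold lower in males, at -3.74 ± 0.74 (SD, n = 3) against -0.77 ± 1.80 (n = 3), a difference of -2.97 ± 0.67 (SE). Complement C3S was 4.41-fold higher in males, at 0.36 ± 1.09 (SD, n = 3) against -1.78 ± 0.50 (n = 3). Zona pellucida glycoprotein 3 differed by -3.47 ± 1.22 (SE), taurine transporter by 0.78 ± 0.47 and pentraxin by 1.19 ± 0.93, and these did not pass. The unnamed probe EA_Pp_67866 (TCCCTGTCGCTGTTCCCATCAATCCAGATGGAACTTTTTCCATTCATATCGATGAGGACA) was lower in males by a log2 difference of -10.96 ± 0.83, at -9.66 ± 0.34 (SD, n = 3) against 1.30 ± 0.46 (n = 3), and EA_Pp_61162 by -8.48 ± 0.79. EA_Pp_63832 was higher in males, by 4.90 ± 0.79. In limma, 1277 of 11755 probes passed (294 higher and 983 lower in males), with adjusted p = 0.0165 for cyclin B1, 0.0476 for complement C3S, 0.0691 for zona pellucida glycoprotein 3, 0.268 for taurine transporter, 0.395 for pentraxin, 4.87e-07 for EA_Pp_67866, 6.64e-06 for EA_Pp_61162 and 0.00705 for EA_Pp_63832.

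EA_Pp_67866 and EA_Pp_61162 passed under all 20 of their alternatives, but the count did not hold. It was 14 without male control replicate 1, 21 without male control replicate 2, 164 (13 higher, 151 lower) without female control replicate 3 and 2519 without female control replicate 2. Without female control replicate 3 cyclin B1 stood at -1.93 (limma adjusted p = 0.0798; 0.00623 to 0.309 over its alternatives) and complement C3S at 2.01 (adjusted p = 0.205; 0.0106 to 0.309). Both calls were also lost without male control replicate 1 or 2, that of complement C3S without female control replicate 1, and that of EA_Pp_63832 without male control replicate 1 (limma adjusted p = 0.0637; 3.14e-04 to 0.309). Egg envelope zona pellucida glycoprotein 3 passed without female control replicate 1 (limma adjusted p = 0.0116) or 2 (adjusted p = 0.0251; 0.0116 to 0.387), but its difference was -0.95 without female control replicate 3 (adjusted p = 0.166), where taurine transporter differed by 0.26 and pentraxin by 0.67. Slide as a block left 8 probes in limma (2 higher, 6 lower), with cyclin B1 at -3.43 (adjusted p = 0.0676) and complement C3S at 2.30 (adjusted p = 0.128). With scan as a block 820 passed in limma (152 higher, 668 lower) and complement C3S stood at 2.29 (adjusted p = 0.0540). Within slide 2 (1 male, 2 females) 1 probe passed, within scan 1 (1 and 2) 12 and within scan 2 (2 and 1) 0 in limma (208 unadjusted). Pairing the fish by number left 1167 probes in limma and complement C3S at adjusted p = 0.0627. Array-median scaling shifted the median of all probes from 0.08 to 0.45 log2 units and gave 1847 probes (1707 higher, 140 lower), of which 428 were shared with the 1277, while the scanner's processed signals gave 642 (264 higher, 378 lower), Cy5 alone 342 (221 higher, 121 lower), the deposited log2 ratios 932 (303 higher, 629 lower), array weights 829 and the compared groups fitted alone 4.

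**Figure D3:**
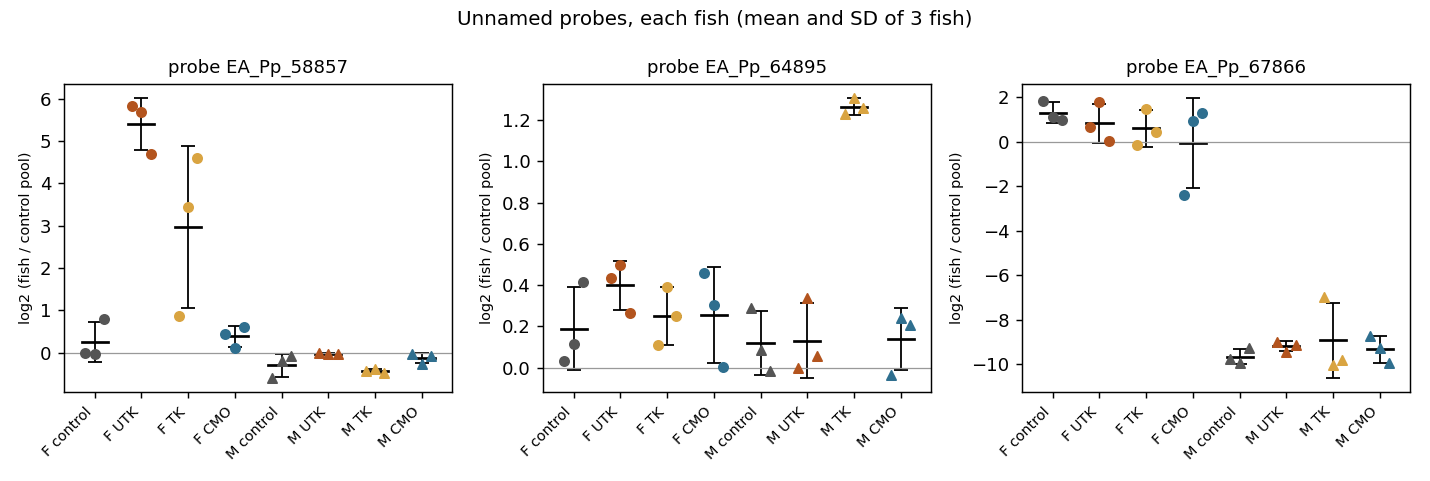
Log2 ratio of each fish to the control pool (vertical axes, log2 units) for 3 probes without a gene name, with each point a fish and each bar the mean and SD of 3 fish, by sex and water. EA_Pp_58857 averages 5.40 in UTK females and 0.25 in control females, EA_Pp_64895 averages 1.26 in TK males and 0.12 in control males, and EA_Pp_67866 averages -9.66 in control males and 1.30 in control females.

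Whether the sexes responded differently was tested as the male change minus the female change. For UTK, cyclin B1 differed by 4.01 ± 0.95 (SE): it was lower in UTK females and higher, without passing, in UTK males than in their controls. Zona pellucida glycoprotein 3 differed by 3.56 ± 1.72, complement C3S by -1.81 ± 0.95, CD18 type 2 by -0.71 ± 0.35 and 149D2R by -0.35 ± 0.19, and these did not pass. For TK, cyclin B1 differed by 2.63 ± 0.95, pentraxin by -3.27 ± 1.32, CD18 type 2 by -0.82 ± 0.35, zona pellucida glycoprotein 3 by 3.36 ± 1.72 and alpha amylase by -2.42 ± 1.26. For CMO, cyclin B1 differed by 2.48 ± 0.95, complement C3S by -1.99 ± 0.95, zona pellucida glycoprotein 3 by 3.20 ± 1.72, pentraxin by -2.14 ± 1.32 and 149D2R by -0.29 ± 0.19. In limma, 911 of 11755 probes passed for UTK (822 up, 89 down), 0 for TK (1895 at an unadjusted p under 0.05) and 0 for CMO (1640 unadjusted). Adjusted p was 0.0201 for cyclin B1 under UTK, 0.215 to 0.286 for the other genes there, 0.226 to 0.349 for those under TK and 0.330 to 0.486 for those under CMO. Leaving out female control replicate 3, the difference in zona pellucida glycoprotein 3 was 1.05 for UTK, 0.84 for TK and 0.68 for CMO, and that in cyclin B1 2.97, 1.60 and 1.44.

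The UTK count was 333 (322 up, 11 down) without female control replicate 3, where cyclin B1 still passed, and 0 in limma without male control replicate 1, male control replicate 2 or UTK male replicate 1. Cyclin B1 then had limma adjusted p = 0.0693, 0.0558 and 0.0608 (0.00313 to 0.713 over its 26 alternatives). The count was 398 and 429 without UTK female replicates 1 and 2, 591 and 426 without UTK male replicates 2 and 3, and 1457 without female control replicate 2. With slide as a block limma called 0 probes (929 unadjusted) and cyclin B1 stood at 2.84 (adjusted p = 0.615), and with scan as a block 626 passed (578 up, 48 down). With scan as a block and without female control replicate 3, 0 passed in limma (1890 unadjusted). With array-median scaling 0 passed in limma (1599 unadjusted), while the scanner's processed signals left 3 probes (1 up, 2 down), Cy5 alone 2 (0 up, 2 down), the deposited log2 ratios 2 (0 up, 2 down), the compared groups fitted alone 3 and array weights 1513. No slide held all 4 groups; within scan 2 (7 fish) limma called 0 (4.84% of probes at an unadjusted p under 0.05), with cyclin B1 at 2.71 (adjusted p = 0.930). The TK count was 4 without TK male replicate 1 and 3 without TK female replicate 1 or male control replicate 3, and the CMO count 1 without male control replicate 3. Blocking on slide gave 0 for both in limma (1243 and 1948 unadjusted), and blocking on scan 0 (1824 and 1604). Within scan 2 limma called 0 for TK (277 unadjusted) and for CMO (207 unadjusted), and within scan 1 0 for CMO (2514 unadjusted). Between the sexes the log2 changes correlated across probes at -0.463 for UTK, 0.187 for TK and -0.109 for CMO, against a simulated median of -0.0168 (-0.301 to 0.281). With the scanner's processed signals they were -0.0535, -0.0066 and 0.0420, and for CMO the correlation was 0.0429 without female control replicate 3.

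**Figure D4:**
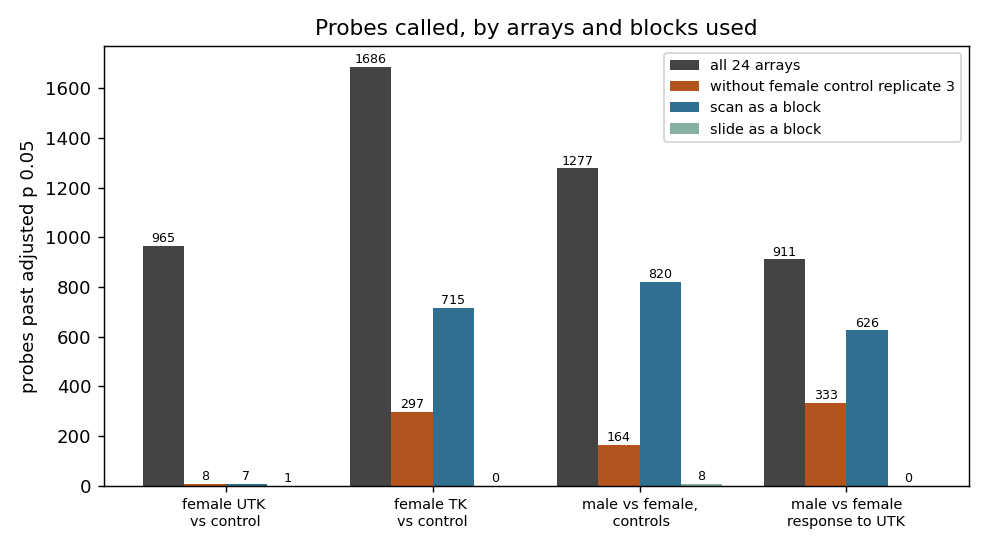
Number of probes past a limma adjusted p of 0.05 (vertical axis) in 4 comparisons, with bars for all 24 arrays, without female control replicate 3, with scan as a block and with slide as a block. The 4 bars are 965, 8, 7 and 1 for UTK females, 1686, 297, 715 and 0 for TK females, 1277, 164, 820 and 8 for male against female controls and 911, 333, 626 and 0 for the response to UTK by sex.

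Differences among the effluents hold for the strengths used (10%, 25% and 100%) only. In females, EA_Pp_58857 averaged 5.40 under UTK, 2.97 under TK and 0.38 under CMO, and EA_Pp_54473 averaged 4.74, 2.42 and 0.18. The order differed in 2 of the other 4 probes that passed, with EA_Pp_65244 at 2.03, 2.11 and -0.08 and EA_Pp_63174 at 1.47, 1.91 and -0.06, while EA_Pp_53222 averaged 3.98, 3.09 and 0.53 and EA_Pp_56301 1.87, 0.58 and 0.38. All 6 were chosen after their values were seen. EA_Pp_65244 and EA_Pp_63174 share a contig number in their names, as do EA_Pp_58857 and EA_Pp_54473, so the probes of each pair may not be separate transcripts. Estrogen receptor alpha averaged 1.26 ± 1.03, 1.02 ± 0.34 and -0.95 ± 1.73 (SD, n = 3) in the same order, and did not pass. In males, EA_Pp_64895 averaged 1.26 under TK and 0.13 and 0.14 under UTK and CMO. In limma's moderated F-test 6 probes passed in females (679 at an unadjusted p under 0.05) and 1 in males (EA_Pp_64895; 1448). Adjusted p was 0.870 for estrogen receptor alpha and alpha amylase, 0.927 for CD18 type 2, 0.939 for pentraxin, 0.953 for cytochrome b and 0.993 for zona pellucida glycoprotein 3 in females. It was 0.306 for pentraxin, 0.312 for alpha amylase, 0.391 for taurine transporter, 0.393 for cyclin B1, 0.694 for complement C3S and 0.978 for zona pellucida glycoprotein 3 in males. The female count was 3 without CMO replicate 2 and 17 without UTK replicate 3, and the male count was 17 without TK replicate 1 and 0 in limma without TK replicate 2 or 3. Array weights gave 26 in females and 1122 in males, and the compared groups fitted alone 0 in females in limma (536 unadjusted). With slide as a block limma called 0 in females (400 unadjusted) and 0 in males (619 unadjusted), and with scan as a block 3 and 0 (1149 unadjusted). Within scan 2 it called 4 in females and 1 in males, and no slide held all 3 exposed groups of a sex.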

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

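Chosen after the result was seen were the tests of turned dyes, of a failed hybridisation, of a wrong label and of ovary RNA in female control replicate 3, and the tests of that fish and of slide 4, with its simulations, as causes of the difference between the sexes under UTK, and the 20 groupings of males; the splits of the fish and the simulated correlations between responses were planned.

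The response to UTK differed between the sexes by limma's test of the difference itself, with 911 probes past an adjusted p of 0.05. Cyclin B1 was among them (male minus female change 4.01), as were EA_Pp_55745 (6.45), EA_Pp_53813 (6.22), EA_Pp_58857 (-4.89) and EA_Pp_54473 (-4.36). EA_Pp_58857 and EA_Pp_54473 rose in UTK females and were well above background in 0 of 3 UTK males and 0 of 3 control males. EA_Pp_55745 was well above background in 0 of 3 UTK males, 1 of 3 control males and 1 of 3 UTK females, so the sizes for these 3 probes are inexact.

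Of 100 splits drawn within each sex, only the real one gave as many as 911 probes (highest other 732). But such splits test for no effect in either sex, not for an equal response, and 92 of them mixed the females and gave at most 1. With the females in their real groups the 20 groupings of males are too few for a share under 0.05 (real 911, highest other 732). Without female control replicate 3 these groupings gave 333 for the real one and at most 3 for the others. The splits thus do not exclude chance for a difference between the sexes. In the unblocked fit female control replicate 3 alone does not account for the whole count, since without it 333 probes passed. The highest of the other splits gave 7, but those splits too test for no effect in either sex. With scan as a block as well, 0 passed in limma (1890 unadjusted). There cyclin B1 went from 2.97 ± 0.72 (SE) to 2.84 ± 0.77 and its call was lost as the error grew (limma adjusted p from 0.0391 to 0.0809, and 0.00313 to 0.713 over its alternatives). Slide 4, which holds all 3 UTK males, remains a possible explanation that no value here decides, since with slide as a block 0 probes passed in limma (929 at an unadjusted p under 0.05) while the log2 differences kept r = 0.864 with those of the unblocked fit and cyclin B1 went from 4.01 ± 0.95 (SE) to 2.84 ± 1.32, a smaller difference with a larger error. Male control replicate 3 shares that slide, and its deviation from the other control males correlated with that of the UTK males at r = 0.723 across probes (0.116 and 0.292 for the other control males), but 10 of 100 simulations without an effect gave as much (median 0.453, -0.856 to 0.839). No CMO or TK male was on slide 4. Its r was also the highest with the CMO males (0.563 against 0.381 and 0.319), but the lowest with the TK males (0.356 against 0.401 and 0.431). A biological difference between the sexes stays open as well, and the design parts it from slide 4 only weakly, through 1 control male on that slide.

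Female control replicate 3 stood apart from the other arrays, with 342 probes over 4-fold higher and 577 over 4-fold lower than in the other control females. Turned dyes are excluded: the pool holds this fish, and over another set of 342 probes, at least 4-fold richer in the pool than in the median exposed fish, the log2 of the mean ratio of the 6 control fish had a median of -0.51 (quartiles -0.66 and -0.35) as labelled and -2.004 (-2.82 and -1.43) with this array turned. Across 8713 probes its ratio followed the level that the pool requires of it by the other 5 control arrays (rho = 0.716). Cy3 on this array followed that of the others at r = 0.996. These values go against a failed hybridisation or scan, or RNA of a fish outside the pool, but do not exclude them. The other controls, which are in the pool as well, gave a rho of only -0.432 to -0.0963. A male under a wrong label is excluded as well, since its sex score was -0.853 against 0.708 to 1.52 in the 12 males, while an exchange of females before pooling was not tested. Ovary RNA in this sample is a candidate explanation that cannot be told apart from a different state of the liver: zona pellucida glycoprotein 3 lay 6.95 log2 units above the highest other array, but 0 markers of the ovary list were readable.

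Whether the resemblance of the 3 female responses came from chance values of the shared controls was not decided by the simulations. Without female control replicate 3 the median of the 3 correlations was 0.740. Simulated unchanged groups gave a median of 0.611 and ranged from -0.530 to 0.904, which is too wide a range to decide. The covariances of 0.178 to 0.286 without that fish lay above the simulated median of 0.152. But that median had risen from 0.0869 when the fish that stood apart was left out. The simulated control mean was then drawn from fewer arrays. Deviations of the other control females were still taken from a group mean that included this fish, so its values were not removed from the simulations. Neither 0.611 nor 0.152 is therefore a yardstick that matches the data without it. Both chance values of the shared controls and a shared response to the effluents stay open.

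For comparisons of 3 fish with 3 the 10 splits are too few for a share under 0.05. As many probes as in the real split were given by 1 split for UTK females (965; highest other 2), 1 for TK females (1686; highest other 1), 10 for CMO females (0; highest other 176), 10 for UTK males (0; highest other 0), 2 for TK males (1; highest other 1), 10 for CMO males (0; highest other 0) and 1 for male against female controls (1277; highest other 1). Of the latter 10 splits, 4 part all 3 same-numbered pairs, and the highest of the 3 others among these gave 1. Where the real split gave 0, every split gives at least as many, so there the splits decide nothing. This also holds for the response by sex to TK (100 of 100 splits; real 0, highest other 1005) and to CMO (100 of 100; real 0, highest other 106). Chance is not excluded for the differences among effluents in females (10 of 100; real 6, highest other 41) and in males (19 of 100; real 1, highest other 5). For the response by sex to UTK the splits mostly tested the female groups: 7 others left the females in their real groups, mixed the males and gave 2 to 732, and 92 mixed the females and gave at most 1. Splits with far more probes than the real one were described after their counts were seen, and their cause was not tested. That with 1005 kept all 4 groups whole with TK and control exchanged in 1 sex, which tests the sum of the 2 changes, and the 10 that kept the females whole and mixed the males gave up to 981. Those with 176 and 106 both put female control replicates 1 and 3 and CMO replicate 2 together.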

How the results depend on the processing

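Chosen after seeing the data were all alternatives of the comparison of exposed males with exposed females, and the fits without female control replicate 3 for the correlations, for results that do not use that fish and together with scan as a block; all other alternatives were planned. No called gene or probe changed sign among 1824 values of named genes and probes under the alternatives. Of these, 1610 had the same outcome as in the main fit, 195 missed the threshold only there and 19 passed it only there. The 1610 include values that passed in neither fit, so they do not give the share of calls that held. Quantile scaling of average intensities, which changes no log2 ratio, is among the alternatives counted. Of 320 counts and correlations, 202 stayed within 1.5 times or 1 SD. EA_Pp_67866 and EA_Pp_61162 passed under all alternatives in controls and in exposed fish, as did EA_Pp_65365 and EA_Pp_65078 in exposed fish. Signals limit all of this: Cy5 was well above background on 45.6% to 65.0% of probe spots. Where no cause is given below, the cause was not tested. The planned set tests with an estimated correlation, fry and means over the probes of a gene were not run, since no list had 3 genes.

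Leaving out each fish in turn, the counts ranged from 8 to 1870 for UTK females, 297 to 2512 for TK females, 0 to 467 for CMO females, 0 to 2 for UTK males, 1 to 44 for TK males, 0 to 1 for CMO males, 14 to 2519 for male against female controls, 0 to 1457 for the response by sex to UTK, 0 to 4 for that to TK, 0 to 1 for that to CMO, 3 to 17 among effluents in females, 0 to 17 among effluents in males and 636 to 887 for exposed males against exposed females. The lowest count for the UTK and TK females came without female control replicate 3, that for the sex difference of controls without male control replicate 1. Only fish of the compared groups were left out for these ranges. Without female control replicate 3, which they share only through the spread, exposed males against exposed females gave 1223.

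Scanner's processed signals gave 6 probes for UTK females, 1 for TK females, 0 for TK males (486 at an unadjusted p under 0.05 in limma), 642 for male against female controls, 3 for the response by sex to UTK, 2 among effluents in females and 0 among effluents in males (456). Median centring in place of loess gave 4 for UTK females, 3 for TK females, 0 for TK males (824 unadjusted in limma), 0 for the response by sex to UTK (1599), 0 among effluents in males (867) and 6299 for exposed males against exposed females, and turned the probes that differed between control males and females from 294 higher and 983 lower in males to 1707 and 140. It moved the median of all probes between females and controls from 0.08 to -0.17 for UTK and from 0.10 to -0.03 for CMO, from -0.01 to 0.12 for TK males, from 0.08 to 0.45 between the sexes of controls, from -0.04 to 0.17 and from -0.05 to 0.07 for the responses by sex to UTK and CMO, and from 0.05 to 0.68 between the sexes of exposed fish. Quantile scaling of average intensities left every count as it was, since it leaves log2 ratios unchanged by construction, and so tests nothing. Cy5 alone gave 4 for UTK females, 0 for TK females (1766 unadjusted in limma), 0 for TK males (467), 342 for male against female controls, 2 for the response by sex to UTK, 3 among effluents in females and 0 among effluents in males (406). The deposited log2 ratios gave 6 for UTK females, 14 for TK females, 0 for TK males (478 unadjusted in limma), 2 for the response by sex to UTK and 0 among effluents in males (452). Normexp with offset 0 left every count within 1.5 times.

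Without a filter, 21495 probes were tested and 550 passed for UTK females, 2716 for TK females, 3 for TK males and 6 among effluents in males. With a filter on all arrays, 8017 probes were tested and 565 passed for UTK females, 926 for TK females, 469 for the response by sex to UTK and 0 among effluents in females (382 unadjusted in limma).

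With slide as a block 1 probe passed for UTK females, 0 for TK females (819 unadjusted in limma), 2 for TK males, 8 for male against female controls, 0 for the response by sex to UTK (929), 0 among effluents in females (400), 0 among effluents in males (619) and 101 for exposed males against exposed females. Blocking on scan gave 7 for UTK females, 715 for TK females, 0 for TK males (685 unadjusted in limma), 820 for male against female controls, 3 among effluents in females and 0 among effluents in males (1149). The replicate block gave 0 for TK males (949 unadjusted in limma) and 0 among effluents in males (1356), and left every other count within 1.5 times: 710 for UTK females, 1539 for TK females, 1167 for male against female controls and 840 for the response by sex to UTK. Same-numbered fish did not deviate together in the comparisons with an effluent (for UTK females r = -0.0850 to 0.0868), so there the block shares only a number. Among the controls, where they did, it ended the call of complement C3S and none other of the named genes. But for that comparison the block was shared by all 24 arrays, so a pairing of the controls alone was not fitted.

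Fitting the compared groups alone, which leaves fewer fish for the spread, gave 0 for UTK females (1817 unadjusted in limma), 0 for TK females (2031), 4 for male against female controls, 3 for the response by sex to UTK and 0 among effluents in females (536). Array weights gave 996 for TK females, 11 for CMO females, 2 for CMO males, 829 for male against female controls, 1513 for the response by sex to UTK, 1 for that to TK, 26 among effluents in females, 1122 among effluents in males and 1585 for exposed males against exposed females; female control replicate 3 had a weight of 0.146.

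With scan as a block and without female control replicate 3, 6 passed for UTK females, 0 for TK females (2032 unadjusted in limma), 133 for male against female controls, 0 for the response by sex to UTK (1890) and 3 among effluents in females. Without that fish in the shared spread, 3 passed among effluents in males. Without it in the control group, the correlation of the CMO responses of females and males went from -0.109 to 0.0429. With the scanner's processed signals the correlation was 0.581 for UTK and TK males (0.220 otherwise), and between the sexes -0.0535 for UTK, -0.0066 for TK and 0.0420 for CMO (-0.463, 0.187 and -0.109 otherwise), so that for TK and CMO its sign changed. Over probes called in either comparison it was -0.773 between the sexes for UTK and 0.562 for TK.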

Other observations

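The comparison of males with females among exposed fish and its overlap with the controls were chosen after the data had been seen; the test of a sex score was planned.

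Among exposed fish (9 males, 9 females), which share no array with the control fish, CD18 type 2 was 1.67-fold lower in males (log2 difference -0.74 ± 0.14 SE) and passed. Estrogen receptor alpha was 3.56-fold lower in males (-1.83 ± 0.55) and missed the threshold, passing under 11 of 31 alternatives. Zona pellucida glycoprotein 3 differed by -0.10 ± 0.70, taurine transporter by 0.53 ± 0.27, alpha amylase by -0.96 ± 0.51 and myocyte enhancer factor 2a by -0.11 ± 0.07, and these did not pass. The SE of zona pellucida glycoprotein 3 rests on a spread that the control females widen, so it overstates the error among exposed fish. Adjusted p in limma was 0.00419 for CD18 type 2, 0.0512 for estrogen receptor alpha, 0.263 for taurine transporter, 0.293 for alpha amylase, 0.334 for myocyte enhancer factor 2a and 0.951 for zona pellucida glycoprotein 3. CD18 type 2 missed the threshold with median centring (adjusted p = 0.0653 in limma) and with slide as a block (0.101; 3.61e-04 to 0.101 over its 31 alternatives). In all, 856 of 11755 probes passed in limma (457 higher and 399 lower in males), and 636 to 887 when a single exposed fish was left out. Female control replicate 3 enters here only through the shared spread, but without it 1223 passed (711 higher, 512 lower). The count was 806 with scan as a block, 101 (31 higher, 70 lower) with slide as a block and 109 (46 higher, 63 lower) within scan 2. Median centring moved the median of all probes from 0.05 to 0.68 log2 units and gave 6299 (6154 higher, 145 lower). Of 100 splits drawn of these fish 1, the real one, gave as many probes and the highest other gave 5, which excludes chance.

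Of the unnamed probes, EA_Pp_67866 was lower in exposed males by a log2 difference of -9.60 ± 0.48 (SE) and EA_Pp_61162 by -7.38 ± 0.46, and both were also called in controls. EA_Pp_65365 was higher in exposed males by 5.01 ± 0.62 and EA_Pp_65078 by 4.47 ± 0.46. In controls EA_Pp_65365 barely passed (limma adjusted p = 0.0498), with males at -3.13 to 2.43 (mean -0.07) against a mean of -3.47 in females, and EA_Pp_65078 did not pass (adjusted p = 0.742), with males at -1.47 to 1.80 (mean -0.20) against -0.62. In exposed fish these 4 probes passed under all 31 alternatives. The 2 lists shared 92 probes higher in males and 73 lower, against 11.4 and 33.4 for independent lists, and 6 probes went opposite ways. Both lists rest on the same spread of each probe, so they are not independent, and probes with a low spread are more readily called in both. Of the 856 probes, 77.5% had the same sign in controls. Without female control replicate 3 the shared counts were 10 and 61, against 0.786 and 6.58, with 1 probe going opposite ways.

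Whether effluents moved male liver towards the female pattern was tested with a score per fish, the mean of the 200 probes most clearly higher in males minus that of the 200 most clearly lower, taken from exposed fish of the other effluents. An exposed fish had a single such score, while a control fish had the mean of its scores on the probe sets of all effluents. Scores of exposed and control fish were thus not built alike, as a permutation test assumes. The 9 exposed males scored 0.00845 above the 3 control males (exact permutation test, two-sided, p = 0.955, adjusted p = 0.955 over 2 tests), and the 9 exposed females lay 0.22 below the 3 control females (exact permutation p = 0.305, adjusted p = 0.609). Neither passed, on a scale where control males averaged 1.08 and control females -0.86. The probes were chosen among exposed fish, which leaves out probes that every effluent had moved towards the other sex, so this test cannot decide the hypothesis.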
